A study of Mus musculus with 2 samples.

How the data were processed

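RNA was compared in mouse embryonic stem cells on 2 Agilent arrays, each carrying RNA from a Tcl1 stable transformant and from a Tcl1 gene disruptant in the 2 dyes Cy5 and Cy3. Per the labels' protocols, cells were grown with LIF on gelatin without feeder cells, total RNA was isolated by acid guanidinium, phenol and chloroform extraction, and labelled cRNA was made with a linear amplification kit. On array 1 the transformant, clone 1, carried Cy5 and the disruptant, clone 4, carried Cy3. On array 2 the dyes were swapped, with transformant clone 4 in Cy3 and in Cy5 a disruptant, clone 6, that had also been transfected with an EGFP vector. For the disruptant of array 1 no vector is stated. The labels describe the arrays as biological replicates of different clones, and give the Tcl1 vector as having been put into disruptant clone 4. The transformants therefore share that origin. Whether disruptant clone 6 also came from clone 4 is not given in the sources used here, so how far the 2 arrays are independent is open. A p-value of a single gene measures only the spread between these 2 pairs of clones. The p-value of a gene list at a preset correlation sets the list against the spread over genes. Its units are genes and not arrays, so it does not measure how far other clones would repeat the result.

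The values used were the authors' deposited table of 1 number per spot and array, with 43790 spots. Per the submitters' processing notes the arrays were processed with Agilent Feature Extraction, and its version, background correction and dye normalization are not given in the sources used here. The deposited values were read as log10 ratios, because that is the scale on which this program writes its log ratio. The median of the deposited values was 0 on array 1 and 0 on array 2, with a range of −2.69 to 1.39 and −2.41 to 1.89. The scale is inferred, how the centring was reached is unknown, and the direction is unstated. The direction was taken as Cy5 over Cy3, which is likely because it is the convention of that program. An exact 0 was found for 2835 spots (6.47%) on array 1 and 3063 spots (6.99%) on array 2, and for 2021 spots on both. Channel intensities were not analysed here, so it is unknown which spots lay above background, and the number of arrays limits the precision.

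Values were multiplied by 3.32 to give log2 ratios, and the sign of array 2 was turned so that both arrays read transformant over disruptant. Probes were named through GEO's annotation of the platform. Of the 43790 spots, 32042 had 1 gene symbol, 47 had several and 11701 were not listed there. Of the probes with 1 symbol, 31906 matched a RefSeq table of assembly GRCm38.p6 by gene number, 0 of them under another symbol. That table was used only for names and for the chromosome of a gene. Of the unlisted spots, 725 lay below −1 in the deposited log10 value on both arrays, which no listed spot did (0). They were treated as control spots and left out, a step that the plan made before the data were examined did not contain. Probes with the same symbol were averaged, and 8266 genes had more than 1 probe. This left 30110 entries, of which 19087 were genes with a symbol and 11023 were single probes without a name. Among the named genes and list members, 264 had several probes, and for 104 of these the probe means differed in sign.

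The mean of the 2 arrays was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 30110 entries and a threshold of 0.05. The fit had 1 residual degree of freedom per gene and 0.861 prior degrees of freedom. A sign-flip test of 2 arrays cannot give a two-sided p below 0.5. The count of genes with at least a 2-fold difference the same way on both arrays was set beside the count in opposite directions, and Pearson and Spearman correlations were computed across genes. The lists of genes, 25 in number, were fixed before the data were examined and tested with camera of limma at a preset correlation of 0.01 between genes, adjusted over the 25 lists. For each list the median was also ranked among those of 10000 random lists of the same size, which were not matched on expression because no intensity was used.

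The genes named were chosen by a rule made before the data were examined. It takes Tcl1 and its family, then in each direction 12 genes past the threshold. Where fewer pass, the places are filled with the genes with the same direction on both arrays and the largest value on the array where it was smaller. It also takes 5 genes with the largest opposite values and the leading members of each list. Genes named outside the rule are said to be so where they appear. The alternatives tried were other centring, single probes, exact zeros left out, array 2 not turned, a log2 reading, 1 array left out, other variance models and thresholds, other fold limits, and estimated, rank-based or narrower list tests. Control spots kept, listed probes alone, the opposite reading of the dyes and list members alone as background were added after the data were seen.

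The procedures were tested on simulated data built on these 30110 entries. With 2 arrays the fit called 0 of the 50 genes changed at each of 2-, 4-, 8- and 16-fold, while the sign was recovered for 100% of them. With 12 arrays it called 48 at 2-fold and 50 at each larger fold, with 0 false calls. The list test found 100% of 200 lists of 35 genes shifted by −0.5 and 2% of unshifted lists. Values were shuffled over genes for this and the lists were random, so their members were uncorrelated by construction. The 2% therefore does not give the rate of false calls for lists whose genes move together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.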

Results

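Gene expression was compared between Tcl1 transformants and Tcl1 disruptants of mouse embryonic stem cells on 2 dye-swapped arrays, each with different clones. In the disruptants both copies of Tcl1, whose protein binds and activates the kinase Akt, had been interrupted by a puromycin cassette. Per the labels, the transformants carried a CAG promoter vector to express Tcl1 again. The sample titles name the aim as finding target genes of Tcl1 in embryonic stem cells. All ratios below are log2 values of transformant over disruptant, given for array 1 and array 2 in that order, and a mean carries its SD with n = 2 arrays. The medians of the deposited values were 0 and 0, and the SD over all entries was 0.464 on array 1 and 0.498 on array 2. The log10 scale is inferred, the way the values were centred is unknown, and the direction, Cy5 over Cy3, is likely from the convention of Feature Extraction but not stated. With the opposite reading every sign below would turn together.

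Tcl1 itself showed no difference past the test between transformants and disruptants. Its 1 probe gave −0.37 and 0.17, a mean of −0.10 ± 0.38 (SD, n = 2) with a limma adjusted p of 1. Whether this probe lies in the replaced part of the gene or in the insert of the vector is not given in the sources used here, so it checks neither the labels nor the direction. The words transformant and disruptant therefore stand for the labels throughout. The relatives of Tcl1 were also near 0. Tcl1b1 had a mean of −0.16 ± 0.17, Tcl1b2 −0.04 ± 0.02, Tcl1b4 −0.09 ± 0.18 and Tcl1b5 0.15 ± 0.14, while Tcl1b3 had −0.0048 ± 0.12. Mtcp1, an X-linked relative, had −0.28 and −0.32. The Tcl1b genes are closely similar in sequence, so their separate values are uncertain. The list of 7 family members had a median of −0.09 and did not pass (camera of limma, adjusted p = 0.278). The 11 measured neighbours of Tcl1 on its chromosome had medians of 0.02 and −0.16 (adjusted p = 0.881).

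The genes furthest below 0 on both arrays were led by Rhox5, Fmr1nb, Calcoco2 and Dppa3. Rhox5, an X-linked homeobox gene, had −3.07 and −4.68, which is a mean of −3.88 ± 1.14 or 14.7-fold lower in the transformants. Fmr1nb, an X-linked neighbour of Fmr1, was 9.64-fold lower (−3.27 ± 0.78), and Calcoco2, a receptor of selective autophagy, 9.33-fold lower (−3.22 ± 0.73). Dppa3, a maternal factor that guards DNA methylation in the zygote, was 5.67-fold lower (−2.50 ± 0.22). Foxj1, a regulator of motile cilia, stood highest above 0 on both arrays, with a mean of 1.48 ± 0.02 or 2.80-fold. None of these differences passed the test over all genes.

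Other genes that the naming rule took as low on both arrays were Rpl39l (−2.51 ± 0.64), Inpp5d (−2.42 ± 0.67), Apobec2 (−2.30 ± 0.53), Nid1 (−2.15 ± 0.61) and Tmem64 (−1.97 ± 0.36). Inpp5d encodes a phosphatase that removes the lipid product of PI3 kinase, and Nid1 a protein of basement membranes. The probes of Rpl39l ranged from −3.02 to −1.99. Eif2s3y, a Y-linked gene for a subunit of a translation initiation factor, gave −4.19 and −1.90 (−3.04 ± 1.61). Oas1a and Oas1b, of the oligoadenylate synthetase family, had means of −1.89 ± 0.07 and −2.20 ± 0.54. Rhox5 and the Oas1 genes belong to gene families, and Eif2s3y has an X-linked copy. Probe sequences were not examined here, so the share of the signal from each is uncertain.

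The genes above 0 on both arrays had smaller values. By the smaller of the 2 array values, Foxj1 was followed by Id1 and Rasl11a. Id1, an inhibitor of basic helix-loop-helix factors, had a mean of 1.21 ± 0.02 (2.32-fold), and Rasl11a 1.17 ± 0.07 (2.26-fold). Mfsd6l had a mean of 1.27 ± 0.45, Fndc4 1.06 ± 0.28, Creld1 1.03 ± 0.22 and Hes6, a relative of the Hes repressors, 1.02 ± 0.05. The histone gene H2bu2 had 0.98 and 1.02, and Mcpt2, C1qtnf6, Cyba and 1500035N22Rik had means of 0.99, 0.93, 0.88 and 0.87.

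Over all 30110 entries limma called 0 genes, with a smallest adjusted p of 1 and a smallest unadjusted p of 0.0025. At an unadjusted limma p under 0.05 there were 947 entries, 507 lower and 440 higher. Uniform p-values would give 1505.5, but that is no fair baseline here, because the 2 arrays ran against each other (Pearson r = −0.19). With array 2 not turned there were 2770, with exact zeros left out 625 and with listed probes alone 488. A further 0 were called with a robust variance model or with treat against a 1.2-fold change. In simulated data 2 arrays gave 0 calls even for 16-fold changes, so a count of 0 does not show that genes were unchanged.

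At least a 2-fold difference in the same direction on both arrays was seen for 58 entries lower in the transformants, 50 of them named genes, and for 5 higher, 3 of them named, which were Foxj1, Id1 and Rasl11a. Opposite directions at that size were seen for 200 entries, 82 of them named genes. In those 200 the same dye was the brighter on both arrays, Cy5 in 101 and Cy3 in 99. The named genes with the largest opposite values were 5031425E22Rik (−3.69 and 2.72), Armcx4 (1.88 and −2.62), Lvrn (−2.02 and 2.15), Tigd2 (1.80 and −1.99) and C230091D08Rik (−2.25 and 1.74). Counted by itself, array 1 had 724 entries lower and 599 higher by 2-fold, and array 2 had 1499 lower and 242 higher. The product of these counts gives 36.0 lower, 4.81 higher and 35.6 opposite for unrelated arrays, against the 58, 5 and 200 found.

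**Figure D1:**
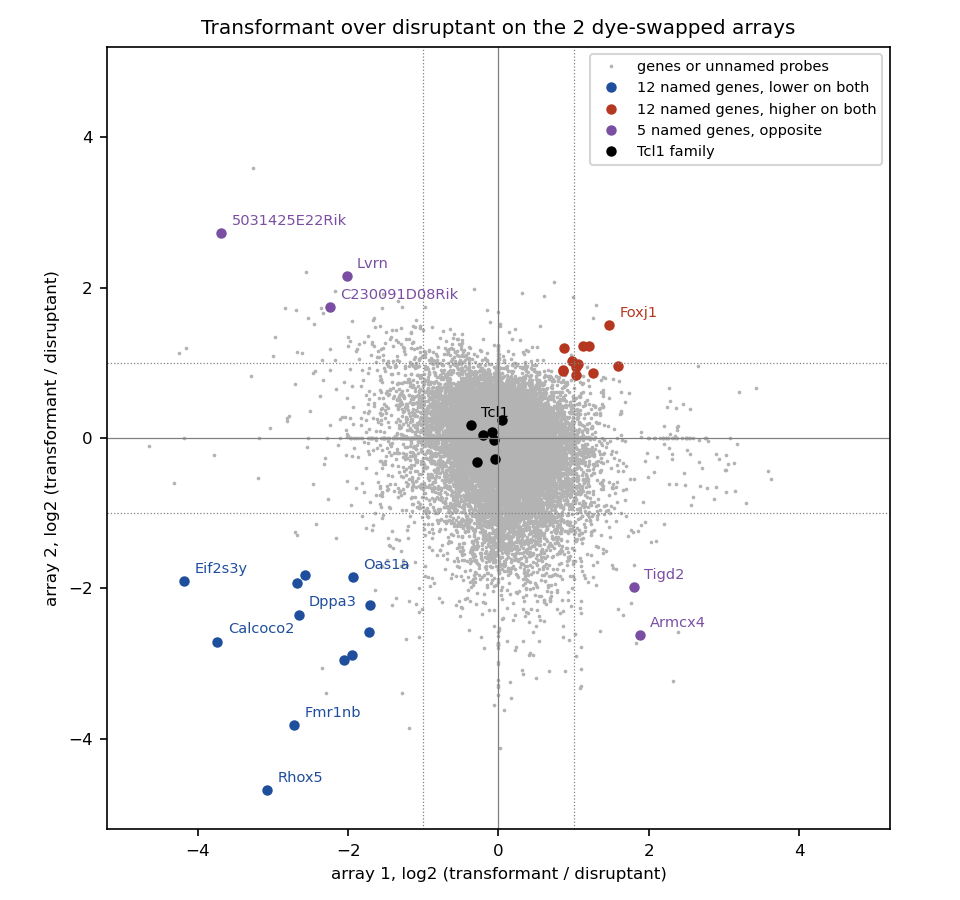
Log2 ratios of transformant over disruptant on array 1 (horizontal) and array 2 (vertical) for 30110 genes or unnamed probes (grey), with the named genes in colour and dotted lines at a 2-fold difference. The cloud slopes down rather than up (Pearson r = −0.19 across genes), and Rhox5, Fmr1nb, Calcoco2 and Dppa3 lie far out at the lower left.

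Across the 30110 entries, with the control spots left out, the values of the 2 arrays ran weakly against each other. The Pearson correlation was −0.19 and the Spearman correlation −0.21. The size depended on the spots used, with a Pearson correlation of −0.84 with control spots kept and −0.14 with listed probes alone. The sign was the same on both arrays for 38.0% of entries, or 41.6% of those that were not 0 on either. These are correlations across genes, which are not independent replicates.

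Genes of the pluripotency network were lower in the transformants as a group in camera of limma at a preset correlation (adjusted p = 1.06e-10), and not with an estimated correlation (adjusted p = 0.762). Of 35 measured members, 22 were below 0 on both arrays, 3 above 0 on both and 10 mixed, with a list median of −0.73 on array 1 and −0.36 on array 2. After Dppa3, the lowest were Fbxo15 (−1.42 and −2.22) and Zfp42, also known as Rex1 (−1.54 and −1.70). Lin28a was low on array 1 (−2.55) and near 0 on array 2 (−0.12), and Rif1 had 1.11 and −0.23. The 2 probes of Rif1 disagreed, with 0.47 and −0.57 for 1 and 1.74 and 0.11 for the other. The core factor Nanog had −0.95 and −1.04, Klf4 had −1.55 and −0.72, and Sox2 had −0.58 and −0.51, genes that the rule did not name and that were chosen after their values were seen. Pou5f1, which encodes Oct4, lay above 0 with 0.10 and 0.50, as did Utf1 with 0.10 and 0.46 and Gbx2 with 0.61 and 1.89.

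The list test with an estimated correlation has 1 degree of freedom, because there are 2 arrays. The estimate was 0.16 for pluripotency genes, but −0.012 for trophoblast markers, below the preset 0.01. For the trophoblast markers the unadjusted camera p still rose from 0.00033 to 0.158. A call lost with an estimated correlation can therefore come from the few degrees of freedom alone, and decides little about a list. The pluripotency median of −0.53 lay at percentile 0 of 10000 random lists. No member passed over all genes (0) or adjusted over the list alone (0), and 11 had an unadjusted p under 0.05. The pluripotency call also ended when array 2 was not turned (median −0.15, camera adjusted p = 0.350). That reading goes against the dye labels, and in it a difference shared by both arrays cancels by construction. Among members that the naming rule did not take, probe means ranged from −1.42 to −0.17 for Tbx3, from −1.55 to −0.10 for Tfcp2l1 and from −1.50 to −0.46 for Jam2.

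**Figure D2:**
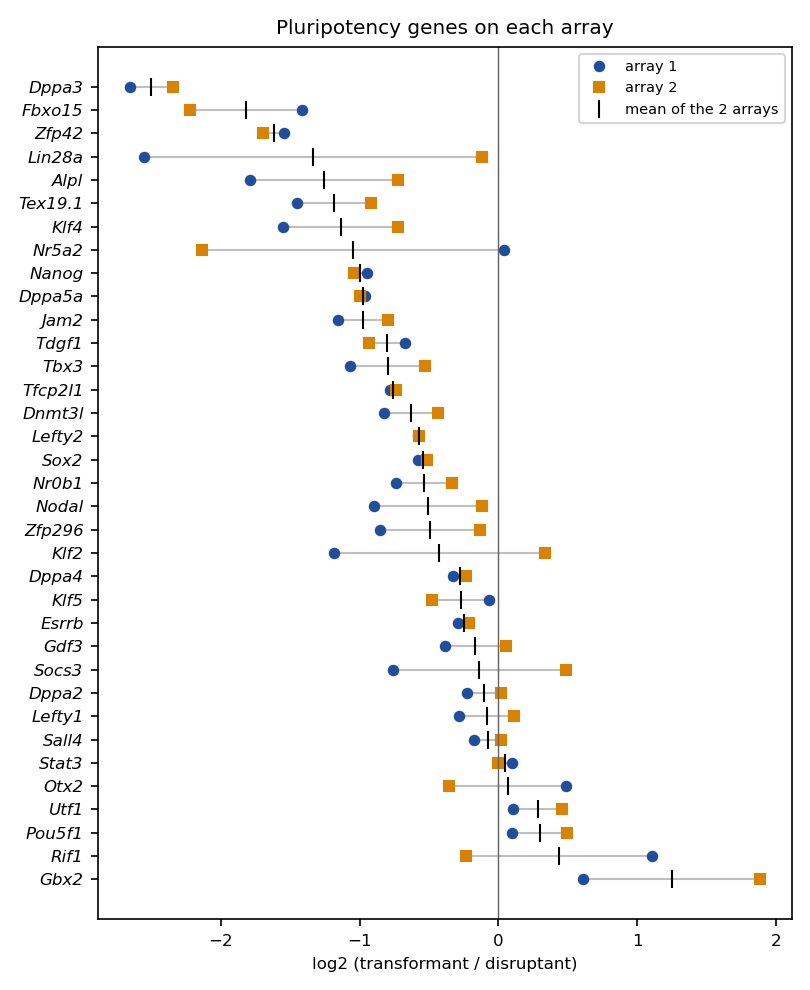
Log2 ratios of transformant over disruptant for the 35 measured pluripotency genes on array 1 (circles) and array 2 (squares), with the mean of the 2 arrays as a black tick. Of these genes 22 lie below 0 on both arrays, and Pou5f1, Utf1 and Gbx2 lie above 0 on both.

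Genes of the germ line and the 2-cell stage were lower as a list at the preset correlation (adjusted p = 0.0092), and not with an estimated correlation (adjusted p = 0.762). Of 25 measured, 12 were below 0 on both arrays and 5 above 0 on both, with medians of −0.19 and −0.29. After Rhox5 the lowest were Sycp3, a protein of the synaptonemal complex (−0.48 and −2.27), Stra8, a regulator of meiotic entry (−1.56 and −0.92), and Tex101 (−1.09 and −0.91). Asz1, a germ-cell gene, was above 0 with 0.79 and 0.32. The call also ended with array 2 not turned (median 0, camera adjusted p = 0.966), where a difference shared by both arrays cancels by construction. The median of −0.24 for the mean over arrays was −0.43 with exact zeros left out and −0.094 with each probe by itself.

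Of 5 lists of markers of other lineages, 3 were lower as lists and 0 higher. Trophoblast markers were lower as a group, with 8 of 21 below 0 on both arrays, 2 above 0 on both and medians of −0.36 and −0.36, and −0.20 for the mean over arrays (adjusted p = 0.0041, and adjusted p = 0.762 with an estimated correlation). Their lowest members were the X-linked homeobox genes Rhox6 (−1.22 and −1.69) and Rhox9 (−1.44 and −1.44) and the transcription factor gene Tfap2c (−0.85 and −0.98), while Hand1 had 0.76 and 0.23. Primitive endoderm markers had medians of −0.16 and −0.075, with 9 of 25 below 0 on both arrays and 2 above (adjusted p = 0.0157, and adjusted p = 0.762 with an estimated correlation). Amn had −1.22 and −0.63 and the laminin gene Lama1 −1.57 and −0.09. Gata4 and Gata6, regulators of that lineage, had mixed signs with means of 0.18 each.

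Mesoderm and primitive streak markers had medians of −0.14 and −0.025, with 8 of 22 below 0 on both arrays and 3 above (adjusted p = 0.0425, and adjusted p = 0.762 with an estimated correlation). Myl7, an atrial myosin light chain gene, had a mean of −1.40 ± 0.15, Snai1 −0.88 and −0.61, and Hand2 0.04 and 0.48. The 2 probes of Hand2 differed, with −0.56 and 0.73 for 1 and 0.65 and 0.23 for the other. With each probe by itself the endoderm and mesoderm calls ended (adjusted p = 0.106 and 0.0711), with the endoderm median at −0.038 against −0.11 and the trophoblast median at −0.11, and with ranks or with listed probes alone the mesoderm call did (0.126 and 0.0809).

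Neural and epiblast markers gave no call (medians −0.0005 and 0.0083, adjusted p = 0.875), with 4 of 21 below and 4 above 0 on both arrays. Fgf5, an epiblast gene, had −0.47 and −1.49, and Sox3 and Pou3f1 had 1.26 and 0.44 and 0.94 and 0.62. Fibroblast markers had medians of −0.06 and 0.11 (adjusted p = 0.886), with Thy1 at −1.06 and −0.91 and Pdgfrb at 1.38 and 0.46. Of these 18 genes, 2 were below and 5 above 0 on both arrays.

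**Figure D3:**
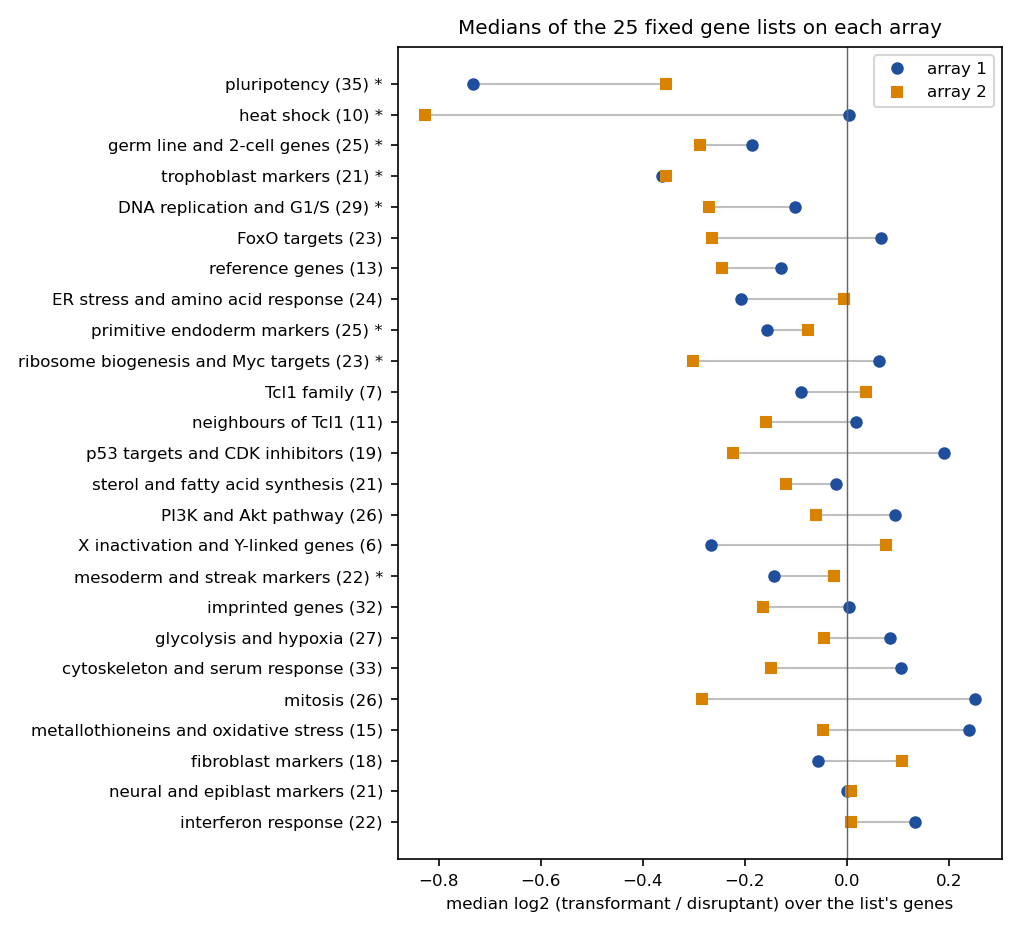
Median log2 ratio of transformant over disruptant for each of the 25 gene lists on array 1 (circles) and array 2 (squares), with the number of measured genes in brackets and an asterisk where the camera adjusted p was under 0.05. The pluripotency list has −0.73 and −0.36, while the heat shock list has 0.0052 on array 1 and −0.83 on array 2.

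DNA replication and G1/S genes had medians of −0.10 and −0.27, with 11 of 29 below 0 on both arrays and 2 above, and were lower as a group (adjusted p = 0.0057, and adjusted p = 0.762 with an estimated correlation). The sliding clamp gene Pcna had −0.10 and −1.57, and Rfc4, a clamp loader subunit, −0.50 and −0.64. Ribosome biogenesis genes and Myc targets had 0.062 on array 1 and −0.30 on array 2, with 7 of 23 below 0 on both arrays and 2 above, and were called lower although their median was below 0 on array 2 alone (adjusted p = 0.0278, and adjusted p = 0.762 with an estimated correlation). Nop58 had 0.35 and −1.80 and Npm1 0.09 and −1.46.

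Heat shock genes had 0.0052 on array 1 and −0.83 on array 2, with 2 of 10 below 0 on both arrays and 0 above, and were called lower on the strength of array 2 (adjusted p = 0.0278, and adjusted p = 0.762 with an estimated correlation). The chaperone genes Hspa8 and Dnaja1 had −0.63 and −1.10, and 0.0050 and −1.75. With only list members as background the pluripotency list alone kept its call (adjusted p = 9.53e-05), and the other 7 had adjusted p from 0.362 to 0.822.

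Reference genes that cells of all kinds express had medians of −0.13 and −0.24 and did not pass (adjusted p = 0.0575), with 6 of 13 below 0 on both arrays and 1 above. Polr2a, the largest subunit gene of RNA polymerase II, had −0.27 and −1.68, and Gusb 0.57 and 0.31. With ranks, or with exact zeros left out, this list passed too (adjusted p = 0.0351 and 0.0442).

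Akt-related genes gave no list call. For the PI3 kinase and Akt pathway the medians were 0.09 and −0.06 (adjusted p = 0.823), with 5 of 26 below and 6 above 0 on both arrays. Inpp5d was the lowest, followed by the kinase subunit gene Pik3cb, with −0.99 and −0.60 as the average of 2 probes. These probes disagreed, with −0.16 and −2.21 for 1 and −1.83 and 1.02 for the other. Bad, a proapoptotic substrate of Akt, had 0.26 and 0.44. Targets of the FoxO factors, which Akt restrains, had medians of 0.07 and −0.26 (adjusted p = 0.126), with 7 of 23 below and 5 above 0 on both arrays. Trp53inp1 had 0.54 and −2.37 and Bcl2l11 had 0.30 and 0.52. The 3 probes of Bcl2l11 disagreed, with −0.46 and 0.92, 1.12 and −0.14, and 0.26 and 0.77. Targets of p53 and inhibitors of cyclin-dependent kinases had 0.19 and −0.22 (adjusted p = 0.514), with 5 of 19 below and 3 above. Pmaip1, which encodes Noxa, had −1.29 and −3.39, and Cdkn2a had 1.42 and 0.80.

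Genes of the cell cycle's later part and of metabolism showed no list call. Mitosis genes had 0.25 and −0.28 (adjusted p = 0.887), with 4 of 26 below and 4 above 0 on both arrays, and Mki67, a proliferation marker, had 2.07 and −0.45. When array 2 was not turned this list was called higher (median 0.28, adjusted p = 0.000286). Glycolysis and hypoxia genes had 0.08 and −0.04 (adjusted p = 0.643), with 7 of 27 below and 8 above, and the glucose transporter gene Slc2a1 had 1.07 and 0.45. Sterol and fatty acid genes had −0.02 and −0.12 (adjusted p = 0.298), with 4 of 21 below and 1 above, and Hmgcs1 had 0.10 and −1.46. Genes of the endoplasmic reticulum stress and amino acid response had −0.21 and −0.0047 (adjusted p = 0.116), with 8 of 24 below and 3 above. Asns, the asparagine synthetase gene, had −1.68 and −1.23.

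Imprinted genes had medians of 0.0039 and −0.17 (adjusted p = 0.226), with 9 of 32 below and 3 above 0 on both arrays. Dio3 and Mirg, of the same imprinted domain, had means of −1.97 ± 1.03 and −1.19 ± 0.43, whereas Meg3 and Dlk1 of that domain, chosen after their values were seen, had means of 0.11 and −0.08. The probes of Slc38a4, another low gene, ranged from −2.03 to −0.10. Genes of X inactivation and the Y chromosome had −0.27 and 0.08 (adjusted p = 0.552), with 1 of 6 below and 2 above, and Xist had −0.28 and 0.32.

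Interferon response genes had 0.13 and 0.0073 (adjusted p = 0.552), with 3 of 22 below and 9 above. Irf7 had 0.85 and 0.43, against the low Oas1a. Cytoskeleton and serum response genes had 0.11 and −0.15 (adjusted p = 0.738), with 6 of 33 below and 9 above, among them S100a10 (−0.72 and −0.86) and Jun (1.06 and 0.01). Metallothioneins and oxidative stress genes had 0.24 and −0.05 (adjusted p = 0.887), with 5 of 15 below and 5 above, among them Gsta4 (−0.64 and −0.66) and Gclm (0.86 and 0.54). With each probe by itself this list was called lower (median −0.23, adjusted p = 0.00906). For the interferon, cytoskeleton, neural, mitosis and metallothionein lists the median, mean and test differed in sign. The medians of the mean over arrays were 0.07, 0.0031, 0.02, 0.0077 and 0.0084 against means over members of −0.01, −0.08, −0.01, −0.00077 and −0.05, and the tests pointed up, down, down, up and up. In none of the 25 lists did a member pass, either over all genes or adjusted over the list alone.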

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

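A group of 725 spots that the platform annotation does not list had deposited log10 values below −1 on both arrays, a signal outside the genes compared. Their medians were −1.99 on array 1 and −1.85 on array 2, which is Cy3 far brighter than Cy5 under the reading used, whichever clone carried the dye, and 0 of the listed spots were that low on both arrays. Their identity is not given in the sources used here.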

How the results depend on the processing

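The count of 0 genes called by limma stayed at 0 under each alternative that gave a count, and leaving out 1 array gave none because no residual degree of freedom remained. Setting each median to 0 moved nothing. Control spots kept, listed probes alone, the opposite dye reading and list members as background were chosen after seeing the data. With each probe by itself there were 104 lower and 9 higher on both arrays and 487 opposite at 2-fold, with r = −0.23 between arrays, and the metallothionein list turned to a median of −0.23 and was called lower (adjusted p = 0.00906). Leaving array 2 unturned goes against the dye labels and cancels a difference shared by both arrays by construction. Without exact zeros r was −0.21 and the germ-line median −0.43. With array 2 not turned there were 99 lower, 101 higher and 63 opposite, r was 0.19, the pluripotency median −0.15 (adjusted p = 0.350), 0 lists were lower and 1 (mitosis) higher, and the medians of ribosome, heat shock and germ-line lists were 0.13, 0.30 and 0. Read as log2, 0 were lower, 0 higher and 0 opposite at 2-fold, because every ratio is then smaller. With control spots kept there were 925 opposite and r was −0.84, and with listed probes alone 3 higher, 82 opposite and r = −0.14. Read as Cy3 over Cy5, signs turn by construction, with 5 lower, 58 higher, 0 lists lower and 8 higher, and medians of 0.53 for pluripotency, 0.20 trophoblast, 0.11 primitive endoderm, 0.049 mesoderm, 0.16 DNA replication, 0.11 ribosome, 0.25 heat shock and 0.24 germ line, and Tcl1 at 0.10. From 1 array at a time the number lower was 724 to 1499, the number higher 242 to 599, Tcl1 −0.37 to 0.17, the pluripotency median −0.73 to −0.36, ribosome −0.30 to 0.062 and heat shock −0.83 to 0.0052. At 1.5-fold there were 286 lower, 109 higher and 1050 opposite, and at 3-fold 15 lower, 0 higher and 24 opposite. Spearman's value was −0.21, and without genes 2-fold on either array r was −0.18. With an estimated correlation, and so 1 degree of freedom, the pluripotency median was −0.53 with a camera adjusted p = 0.762, and 0 lists were lower. With list members as background 1 list was lower. Of 218 named genes, 218 changed sign with the opposite dye reading, 130 with array 2 not turned, 26 on array 2 alone and 47 on array 1 alone. With the set of single probes 11 did, and without zeros 2. The number was 0 with the median set to 0, a log2 reading, control spots kept or listed probes alone. These last settings cannot turn the sign of a named gene here, so the 0 holds by construction. Where no construction explains a shift, the cause was not tested. Each array pairs 1 transformant with 1 disruptant, and the tested value is their ratio, so no further pairing was possible. Signal over background was not analysed here.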

Other observations

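Relatives of Rhox5 and of Oas1a, chosen after their values were seen, had values of both kinds. In the Rhox cluster Rhox6, Rhox9 and Rhox13 had means of −1.46 ± 0.34, −1.44 ± 0.0023 and −0.95 ± 0.04 (SD, n = 2) beside Rhox5, while Rhox11 had 0.83 and −0.06. In the Oas1 family Oas1f had a mean of −1.48 ± 0.40 and Oas1d −0.80 and −0.74, Oas1g −0.16 and −0.54, while Oas1c, Oas1e and Oas1h had mixed signs. Members of a family can be similar in sequence and probe sequences were not examined here, so the values of single members are uncertain. Outside these families and outside the naming rule, 4 more genes were chosen after their values were seen. Cth and Cdo1, which make and oxidise cysteine, had −1.42 and −1.24, and −1.21 and −1.22. Tcf15, a transcription factor gene, had 0.73 and 2.07, and Mcf2 had −1.19 and −3.85. None of these passed the limma test (adjusted p = 1 for each).

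Of the tests below, the comparison of pluripotency genes with lists of expressed genes was chosen before its result was seen, and the others were chosen after. Among the autosomes and X, medians by chromosome were largest in size on chromosome 12, at −0.11 on array 2 (size 0.115, largest standard error 0.034), below the 0.29 that a gained or lost chromosome was taken to need. Genes below background would pull such a median toward 0, and it is unknown which genes these are. A gain or loss, in all or part of the cells, therefore stays open.

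The low pluripotency list was weighed against 3 technical explanations. A dye bias of these probes would turn sign with the swap, but the median was below 0 on both arrays, at −0.73 (95% bootstrap interval −0.89 to −0.29) and −0.36 (−0.72 to −0.12). A bias common to genes expressed in these cells was tested on 117 genes of 5 lists, whose medians were 0.04 and −0.19. The test asked for a lower pluripotency median on each array, and its one-sided permutation p over genes, which are not independent, was 1e-05 on array 1 (the smallest that 100000 permutations can give) and 0.116 on array 2, so this bias stays open. Differentiated cells in the transformant cultures also stay open. The highest median of a lineage list was 0.023 for the mean over arrays (0.11 on array 2 for fibroblast markers). Which markers lay above background is unknown, however. An effect of Tcl1 or of clonal differences may also account for the pattern and was not tested. No vector is stated for the disruptant of array 1, so there an effect of Tcl1 cannot be told apart from that of transfection itself.

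More genes were 2-fold lower than higher on both arrays, 58 against 5. A skewed spread of each array may give such a difference with unrelated arrays, and shuffling genes between arrays 10000 times gave means of 36.1 lower and 4.83 higher. The shuffles are no fair baseline, however, because they gave a mean of 35.6 genes in opposite directions where 200 were found, so the arrays are not unrelated at this size. Whether the 58 exceed what skew and the spread of single genes give therefore cannot be told apart here, and an effect of Tcl1 was not tested.

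The low value of Eif2s3y may reflect loss of the Y chromosome from part of the cells. The other 12 Y-linked genes had a median of 0.032, with −0.03 on array 1 and 0.12 on array 2. Of these, 2 were below 0 on both arrays, among them Uba1y, a gene outside the naming rule, with −1.31 and −0.70. Since many Y-linked genes may lie below background in these cells, that median decides nothing. Eif2s3x, the X-linked copy of Eif2s3y and also outside the naming rule, had −0.49 and −1.17, so it was lower too, but by less on each array. Eif2s3y lay below Eif2s3x by differences of −3.70 and −0.74. The smaller, −0.736, is within the SD of 1.61 of Eif2s3y between arrays, a spread that the low value on array 1 itself widens. That SD comes from the same 2 values of Eif2s3y, so this test could hardly decide. Signal from Eif2s3x would draw the values of Eif2s3y toward −0.49 and −1.17, yet they were lower, at −4.19 and −1.90. A share of signal from Eif2s3x stays open, but as the only source it would not give the −4.19 of array 1.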
